A study of Mus musculus with 10 samples.

How the data were processed

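The deposited table holds 13809 genes in 10 libraries, and the signal values in it are gene read counts that the authors divided by 1 factor per library before depositing them. This was tested on the table: values above the floor of 1 and under 1000 reads are whole multiples of 1 step per library, between 0.892 and 1.35, within a tolerance of 0.02 in 100% of cases. The floor is the lowest value of every library and was left out of this test, and every gene reaches at least 10.1 in some library, so genes with fewer reads were left out upstream. The submitters' processing notes name HISAT 0.1.7 and the mouse genome build mm10. Read trimming, the gene annotation and the program that counted reads are not given in the sources used here. Recovered read totals were obtained by dividing each value by the step of its library, and they assume that this step is 1 read.

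Groups were taken from the labels, all 10 libraries were used, and no library was left out of the main analysis. Values were analysed as log2 of the value plus 1 with limma 3.58.1 in R 4.3.3. Genes at 10 or more in at least 2 libraries were tested, which kept 13755 genes and left out 54. A single linear model with the 4 groups was fitted to all 10 libraries (6 residual degrees of freedom), and variances were moderated with a trend on the mean level. Of the 5 contrasts, 2 are LPS against untreated within each origin, 2 are resident against BMDM within each treatment, and the last is the difference of the LPS responses. P-values from limma are 2-sided and adjusted by Benjamini and Hochberg's method within each contrast, and a gene is called at an adjusted p under 0.05. Words such as rose, fell, higher and lower of a single gene refer to called genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

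The 33 gene lists were written from general knowledge before the data were examined. They hold 788 genes, of which 758 are in the table and 757 were tested. They cover macrophage identity, island macrophages, iron handling, erythroid cells, neutrophils, B lineage, plasma cells, T and NK cells, megakaryocytes and platelets, stem and progenitor cells, dendritic cells, monocytes, eosinophils with basophils and mast cells, stroma and bone, and osteoclasts. The others are proinflammatory cytokines, chemokines, type I interferon response, NF-kB feedback, anti-inflammatory genes, antimicrobial genes, TLR signalling, antigen presentation, complement, apoptotic cell clearance, cholesterol and lipid genes, lysosome, cell cycle, glycolysis and hypoxia, NRF2 and oxidative stress, immediate-early and stress genes, mitochondrial respiration, and matrix and adhesion. Lists were tested against all other genes with limma's camera test at a preset correlation between genes of 0.01, for lists with at least 5 members, and p-values were adjusted over the lists within a contrast. Genes were also adjusted over the members of each list alone.

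Genes named in the text follow a rule fixed before the data were examined. The rule names 16 genes in every contrast and, per contrast, the 8 largest rises and 8 largest falls among called genes whose libraries do not overlap between groups and whose mean is at least 20 in the higher group. For the difference of responses there was no requirement on overlap. For each list it adds up to 2 called rises and 2 called falls. Predicted genes without a name, mitochondrial genes and ribosomal pseudogenes were left out of the largest changes. Chance separates the groups of a gene without overlap in 10% of cases for 3 libraries against 3, 20% for 3 against 2 and 33.3% for 2 against 2. Where all libraries of a group are at the floor, a fold is a lower bound against 3 reads per library, and medians of lists are also given with such genes at that bound. Y-linked genes, Xist and Rn45s were named after their values were seen, and 4 X-linked genes were chosen for a test before their values were seen. Genome positions come from the GENCODE annotation. Of the gene symbols in the deposited data, 13370 were found in a separate reference list of gene names and 439 were not. Sets of genes with identical values in every library (16 genes in 7 sets) and near-identical gene copies such as the beta globins cannot be resolved from each other in this table.

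Alternatives fixed in advance were pseudocounts of 0.1 and 10, no filter on low values and a filter at 100, quantile normalization, recomputed median-ratio factors, limma without the trend and with robust moderation, array weights, fitting only the groups compared, a minimum log2 change of 1, an estimated correlation between genes and limma's fry rotation test for lists, and leaving out each library in turn. Alternatives chosen after seeing the data were equal library totals with and without Rn45s, voom on recovered reads, a term for libraries with Y-linked transcripts, and leaving out both of these libraries. The analysis was tested on simulated data with known changes of 1.5-fold, 2-fold and 4-fold. For LPS in resident macrophages it recovered 40.3%, 83.6% and 97.0% of them, and for the difference of responses 11.9%, 64.2% and 86.4%. Between 4 and 12 of at least 13310 unchanged genes were called in a contrast. The simulation changed a small share of genes in a single group, with independent libraries and the same spread in all groups. The real data have far more changes, unequal spread between origins and medians that move with the scaling, so these rates need not carry over.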

Results

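Gene expression was measured by RNA sequencing in 10 libraries from the bone marrow of C57BL/6 mice aged 12 weeks. The cells were macrophages of 2 origins. Resident macrophages, described by the submitters as CD163-positive, are ferromagnetic cells that a magnetic column retained without any staining. Bone marrow derived macrophages (BMDM), described as CD163-negative, were grown from the flow-through of the same column with 20% L929 cell supernatant, which supplies macrophage growth factor, for 6 days by the growth protocol and 7 days by the sample titles. Cells of each origin were left untreated or given 1 µg/ml lipopolysaccharide (LPS), a bacterial cell wall component that activates Toll-like receptor 4, for 4 h. There were 3 libraries of untreated and 3 of LPS-treated resident macrophages, and 2 libraries of untreated and 2 of LPS-treated BMDM. Gene read totals recovered from the table ran from 27.1 to 37.7 M per library, and the deposited normalized values summed to between 24.7 and 38.8 M. Values below are normalized reads as mean ± SD, and changes are log2 ± SE. The labels do not say whether replicates come from separate animals or cultures, so p-values measure the spread between these libraries, pooled over the 4 groups.

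Across genes, Pearson correlations of log2 values within a group ran from 0.982 to 0.995. Untreated and LPS-treated resident libraries correlated at 0.971 to 0.986, untreated and LPS-treated BMDM at 0.896 to 0.898, and untreated libraries of the different origins at 0.807 to 0.830. Replicate 1 of each resident group stood apart from the other libraries: the Y-linked genes Ddx3y (1856 and 1975), Eif2s3y, Kdm5d and Uty were read in these libraries alone. Xist, which is transcribed from the inactive X chromosome, stood at 1651 and 2172 there and at 7873 to 13871 in the other 8 libraries. Rn45s, a ribosomal RNA precursor, took 4.70% of the values of untreated BMDM replicate 2 and between 0.151% and 1.34% of every other library.

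The comparison of LPS-treated with untreated resident macrophages asks which genes LPS changes in the cells that the column retained. LPS raised inflammatory cytokine transcripts in this fraction. Its libraries also carry transcripts of neutrophils and other marrow cells, described below, so a change cannot be assigned to macrophages alone. Here and below, resident macrophages is the label of this fraction. Il1b rose from 26836 ± 6296 to 109554 ± 9540 (n = 3 and 3), a change of 2.05 ± 0.15. Tnf rose by 1.34 ± 0.12, and Il12b, which encodes a subunit of interleukin 12, rose by 3.22 ± 0.29 from 35.6 ± 15.4 to 319 ± 13.4. Ptx3, which encodes a secreted pattern recognition protein, rose by 4.44 ± 0.42, and the chemokine gene Ccl3 rose by 2.76 ± 0.22. Fbxo32, a ubiquitin ligase subunit gene, fell from 1184 ± 286 to 129 ± 30.1 (-3.18 ± 0.20), and Arg1, which encodes arginase 1, fell from 454 ± 56.0 to 134 ± 9.41 (-1.74 ± 0.17). Tlr4, the LPS receptor gene, fell by 0.85 ± 0.10, and Slc40a1, which encodes the iron exporter ferroportin, fell by 0.92 ± 0.15.

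Of the other genes fixed in advance, Ifnb1 rose by 2.28 ± 0.21 (adjusted p = 0.000242). Il6 rose by 2.40 ± 0.49, a call that array weights ended (2.17, adjusted p = 0.0786). Il10 rose by 1.79 ± 0.38, which was not called when only the resident libraries were fitted (adjusted p = 0.086). Nos2, the inducible nitric oxide synthase gene, rose by 1.97 ± 0.47 (adjusted p = 0.0227), but not without LPS replicate 1 (1.83, 0.0582) or LPS replicate 2 (1.96, 0.0705), without the variance trend (0.0551), with the resident libraries alone (0.0642) or with array weights (0.0516). Cxcl10 rose by 0.68 ± 0.15 (adjusted p = 0.0186), a call lost without LPS replicate 2 (0.63, 0.0689), with quantile normalization (0.51, 0.0671) and with the resident libraries alone (0.145). Hmox1, which encodes heme oxygenase 1, had a change of -0.67 ± 0.19 at an adjusted p of 0.0457, and the call was lost in 12 of the other settings, 8 of them without 1 library (values of -0.74 to -0.51). Cd163 (-0.49 ± 0.24), Vcam1 (-0.01 ± 0.14), Spic (0.08 ± 0.14), Adgre1 (-0.01 ± 0.20) and Cd14 (0.65 ± 0.30) were not called. Without untreated replicate 1, Cd14 was called at 1.02 (adjusted p = 0.0111), while Vcam1 and Adgre1 turned to 0.15 and 0.24. With a term for libraries with Y-linked transcripts, Cd163 (adjusted p = 0.0145) and Cd14 (adjusted p = 0.000679) were called at the same values. Cd14 was also called with array weights (0.75, adjusted p = 0.0212) and without both of these libraries (0.77, adjusted p = 0.00134), but its change was 0.43 with quantile normalization, 0.41 without untreated replicate 3 and 0.40 without LPS replicate 1.

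Gene lists were fixed before the data were examined, and where no count adjusted over the list alone is given it equals the count given. Of these lists, 20 of 24 proinflammatory cytokine genes rose and none fell in the resident cells (22 adjusted over the list alone), with a median of 1.80. The list passed limma's camera test (adjusted p = 7.08e-35) and did not with an estimated correlation (adjusted p = 0.116). NF-kB feedback genes, a list that also holds other NF-kB targets such as Ptgs2, rose in 30 of 33 cases (32 adjusted over the list alone), with a median of 0.70 (adjusted p = 2.29e-53, adjusted p = 0.274 with an estimated correlation). Examples are Ptgs2 (2.70 ± 0.33) and Tnip3 (2.00 ± 0.13). Of 47 type I interferon response genes 39 rose and none fell (44 rose and 1 fell adjusted over the list alone), with a median of 0.54 (adjusted p = 1.83e-24, adjusted p = 0.408 with an estimated correlation), as in Ifi205 (1.13 ± 0.19). Chemokine genes rose in 13 of 23 cases (14 adjusted over the list alone), with a median of 0.91 (adjusted p = 1.91e-15, adjusted p = 0.408 with an estimated correlation), as in Ccl17 (3.82 ± 0.38, or 2.26 with a pseudocount of 10). Antimicrobial genes rose in 14 of 26 cases (14 adjusted over the list alone), with a median of 0.75 (adjusted p = 1.4e-12, adjusted p = 0.274 with an estimated correlation), among them the acute phase gene Saa3 (2.92 ± 0.24). TLR signalling genes rose in 11 and fell in 4 of 41 cases (17 and 7 adjusted over the list alone), with a median of 0.20 (adjusted p = 6.39e-05, adjusted p = 0.511 with an estimated correlation). Irak3 (1.39 ± 0.07) and Nlrp3 (1.31 ± 0.08) rose in this list, and Tlr5 fell (-2.09 ± 0.36, or -1.01 with a pseudocount of 10). Lysosome genes fell in 10 and rose in 1 of 35 cases (11 and 2 adjusted over the list alone), with a median of -0.25 (adjusted p = 0.000149, adjusted p = 0.659 with an estimated correlation). The riser was Ctsk, a cathepsin gene of osteoclasts (0.97 ± 0.11).

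Further lists passed the camera test, but leaving out a single library ended each of these calls. Island macrophage genes, which mark the central macrophages of erythroblastic islands, fell in 5 of 22 cases (8 adjusted over the list alone), with a median of -0.28 (adjusted p = 0.0015, adjusted p = 0.659 with an estimated correlation). Without untreated replicate 1 that median was -0.12 (adjusted p = 0.129). Macrophage identity genes fell in 3 of 15 cases (3 adjusted over the list alone), with a median of -0.24 (adjusted p = 0.00399, adjusted p = 0.659 with an estimated correlation) and of -0.12 without untreated replicate 1 (adjusted p = 0.113). Aif1 fell by 0.66 ± 0.07. Antigen presentation genes rose in 5 of 22 cases (6 adjusted over the list alone, median 0.17, adjusted p = 0.0114, adjusted p = 0.66 with an estimated correlation), a call lost without untreated replicate 3 (0.05, adjusted p = 0.0642) or LPS replicate 1 (0.07, adjusted p = 0.205). Immediate-early and stress genes rose in 8 and fell in 4 of 28 cases (10 and 5 adjusted over the list alone, median 0.14, adjusted p = 0.0187, adjusted p = 0.511 with an estimated correlation), and the call was lost without LPS replicate 3 (0.05, adjusted p = 0.142). In that list Nr4a3 rose by 1.83 ± 0.12 and Hspa1a fell by 1.19 ± 0.23. Plasma cell genes rose in 2 of 8 cases, Irf4 (1.03 ± 0.08) and Prdm1 (0.74 ± 0.10), with a median of 0.08 that turned to -0.04 with equal library totals (2 adjusted over the list alone, adjusted p = 0.0187, adjusted p = 0.511 with an estimated correlation). That call was lost without untreated replicate 2 (0.06, adjusted p = 0.0537) or LPS replicate 1 (-0.05, adjusted p = 0.0851). Mitochondrial respiration genes fell in 1 of 34 cases (1 adjusted over the list alone, median -0.10, adjusted p = 0.0187, adjusted p = 0.66 with an estimated correlation), which was lost without untreated replicate 1 (-0.10), untreated replicate 2 (-0.08) or LPS replicate 3 (-0.05).

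The other 20 lists did not pass the test in this comparison. Iron handling genes rose in 6 and fell in 8 of 31 cases, with a median of -0.07 and a mean of 0.05 (10 and 10 adjusted over the list alone). Steap4 (2.44 ± 0.24) rose and Hfe (-0.99 ± 0.13) fell. Erythroid genes rose in 2 of 32 cases (1 adjusted over the list alone), and neutrophil genes rose in 6 and fell in 2 of 33 (7 and 3). No megakaryocyte (19 genes), stem and progenitor (15), eosinophil, basophil and mast cell (17) or cell cycle (39) gene was called by limma. Glycolysis and hypoxia genes rose in 4 and fell in 3 of 25 cases (5 and 6), and NRF2 and oxidative stress genes rose in 3 and fell in 5 of 23 (3 and 6), with Slc7a11, a cystine transporter gene, at 1.62 ± 0.13. Among T and NK cell genes Ifng rose by 2.38 and Gzmb by 1.23, and no member fell. That list took 0.139% of untreated and 0.213% of LPS-treated resident values. In BMDM it took 0.0461% and 0.225%, and its member Ccl5 rose there by 9.16 with LPS. A change of this share is thus no measure of T and NK cells. B lineage genes had a median of 0.09 where the test pointed down.

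In all, limma called 1779 of 13755 genes at an adjusted p under 0.05, 1013 higher and 766 lower, of which 226 rose and 85 fell at least 2-fold. The count rests on the spread pooled over all 10 libraries: the 6 resident libraries alone gave 529 genes, leaving out untreated replicate 3 gave 1185 and LPS replicate 2 gave 970, and without both libraries with Y-linked transcripts it was 2840. With equal library totals, which put the median of all genes at -0.12, 2388 genes were called and 27.1% of them were higher, against 56.9% with the deposited values.

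**Figure D1:**
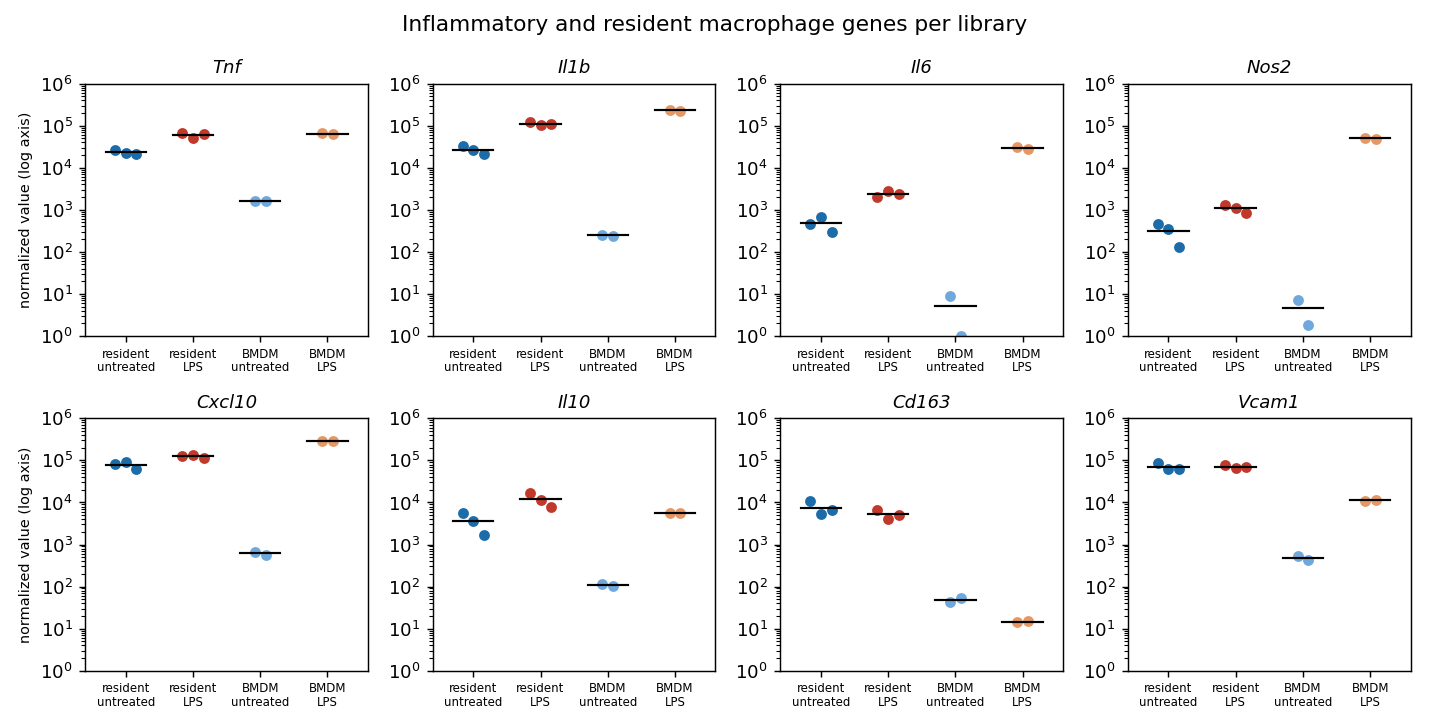
Normalized reads (log axis) of 8 genes in each of the 10 libraries, by group, with the group mean as a line. Tnf, Il1b and Cxcl10 stand far higher in untreated resident libraries than in untreated BMDM, while after LPS the mean of Tnf is 59809 in resident macrophages and 65021 in BMDM.

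The same comparison in BMDM asks which genes LPS changes in macrophages grown in culture. LPS raised inflammatory genes there, some of them from near the detection limit. Nos2 rose from 4.56 ± 3.86 to 50665 ± 1933 (n = 2 and 2), a change of 13.35 ± 0.58, and Il6 rose from 5.06 ± 5.74 to 29282 ± 2022 (12.67 ± 0.60). Il1b rose by 9.89 ± 0.19, Il12b by 8.41 ± 0.36 and Tnf by 5.30 ± 0.15. Ifnb1, the interferon beta gene, was at the floor in both untreated libraries and at least 103-fold higher after LPS, taking 3 reads per library as the floor. Cnr2, a cannabinoid receptor gene, fell from 1617 ± 44.1 to 23.0 ± 3.81 (-6.08 ± 0.33), and Thbd, which encodes the anticoagulant receptor thrombomodulin, fell from 707 ± 112 to 10.7 ± 2.08 (-5.92 ± 0.24).

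Other large rises in BMDM were those of Cxcl11 (10.54 ± 0.35), Il27 (10.23 ± 0.30), the endothelial lipase gene Lipg (10.13 ± 0.31), Cxcl9 (9.96 ± 0.25) and Il1a (9.96 ± 0.25), and other large falls those of Pald1 (-6.05 ± 0.17), Plekhg3 (-5.65 ± 0.19), Aatk (-5.30 ± 0.35) and the proapoptotic gene Bmf (-5.17 ± 0.32). Cxcl10 rose by 8.87 ± 0.19 and Il10 by 5.64 ± 0.47. Vcam1, an adhesion molecule gene that marks resident bone marrow macrophages, rose by 4.54 ± 0.18, and Spic, a transcription factor gene of iron-recycling macrophages, by 2.45 ± 0.17. Cd163, the receptor gene for hemoglobin and haptoglobin complexes, fell from 47.9 ± 8.48 to 14.6 ± 0.357 (-1.63 ± 0.30), a call that voom on recovered reads did not make (adjusted p = 0.25). Slc40a1 fell by 0.91 ± 0.19, and by 1.52 with equal library totals. Hmox1 fell by 0.85 ± 0.23, a call lost without untreated replicate 1 (-0.77, adjusted p = 0.073) or LPS replicate 2 (-0.67, adjusted p = 0.108), and the change was -1.67 with quantile normalization and -1.46 with equal totals. Adgre1 (0.45 ± 0.25) and Tlr4 (-0.14 ± 0.12) were not called, and Adgre1 turned to -0.55 with quantile normalization and -0.16 with equal totals. Without resident untreated replicate 1, Adgre1 was called at 0.45 (adjusted p = 0.0215). Cd14 rose by 1.70 ± 0.37, but had 0.50 with quantile normalization (adjusted p = 0.179).

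All 47 type I interferon response genes rose in BMDM, with a median of 5.93 (47 adjusted over the list alone, adjusted p = 2.04e-137, adjusted p = 0.246 with an estimated correlation), among them Gbp5 (9.61 ± 0.19) and Ifi205 (9.25 ± 0.23). All 24 proinflammatory cytokine genes rose, with a median of 6.33, or 6.19 with genes at the floor set at their bound (24 adjusted over the list alone, adjusted p = 8.75e-34, adjusted p = 0.206 with an estimated correlation). All 33 NF-kB feedback genes rose, with a median of 3.15 (33 adjusted over the list alone, adjusted p = 1.05e-46, adjusted p = 0.253 with an estimated correlation), for example Ptgs2 (9.49 ± 0.40) and Socs3 (8.10 ± 0.26). Chemokine genes rose in 19 of 23 cases (median 6.00, or 5.94 at the bound, adjusted p = 3.91e-19, adjusted p = 0.283 with an estimated correlation). Antimicrobial genes rose in 17 and fell in 2 of 26 cases (median 2.41, adjusted p = 1.29e-14, adjusted p = 0.246 with an estimated correlation). TLR signalling genes rose in 31 and fell in 6 of 41 cases (median 1.08, adjusted p = 2.31e-10, adjusted p = 0.246 with an estimated correlation): Nod1 rose by 5.46 ± 0.10 and Tlr13 fell by 2.08 ± 0.24. Antigen presentation genes rose in 15 of 22 cases (median 1.22, adjusted p = 7.31e-08, adjusted p = 0.52 with an estimated correlation), with Cd40 at 8.25 ± 0.32.

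Anti-inflammatory genes rose in 13 and fell in 5 of 24 cases in BMDM (median 0.67, adjusted p = 0.00247, adjusted p = 0.613 with an estimated correlation): Irg1, whose product makes itaconate, rose by 8.42 ± 0.14 and Vegfa fell by 2.66 ± 0.21. Complement genes rose in 7 and fell in 1 of 22 cases, with Cfb at 8.83 ± 0.22. The list's median was 0.01 and its mean 1.23 (adjusted p = 0.0269, adjusted p = 0.724 with an estimated correlation). The median turned to -0.11 with quantile normalization and -0.42 with equal totals, and the call was lost without resident untreated replicate 1 (0.0562). Cell cycle genes fell in 28 and rose in 2 of 39 cases (30 and 2 adjusted over the list alone, median -1.06, adjusted p = 0.00519, adjusted p = 0.951 with an estimated correlation), as in Kif23 (-2.61 ± 0.28) and, rising, Ccne1 (2.07 ± 0.26). With equal totals the list had a median of -1.67 and was not called (0.107). Cholesterol and lipid genes fell in 17 and rose in 2 of 32 cases (median -0.52, adjusted p = 0.00616, adjusted p = 0.327 with an estimated correlation), as in Scd2 (-3.82 ± 0.23) and Dhcr7 (-2.75 ± 0.24). Of the remaining lists, glycolysis and hypoxia genes rose in 15 and fell in 3 of 25 cases, with a median of 0.69 that turned to -0.08 with quantile normalization. Mitochondrial respiration genes rose in 13 and fell in 1 of 34 (10 and 1 adjusted over the list alone), with a median of 0.20 that turned to -0.33 and -0.42. NRF2 and oxidative stress genes rose in 5 and fell in 12 of 23 cases.

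Limma called 7953 genes in BMDM, 3896 higher and 4057 lower, and 2187 rose and 2122 fell at least 2-fold. The balance of directions depends on the scaling: equal totals put the median of all genes at -0.64 and quantile normalization at -0.21, against -0.04. The called genes were then 21.7% and 40.0% higher, against 49.0% with the deposited values.

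**Figure D2:**
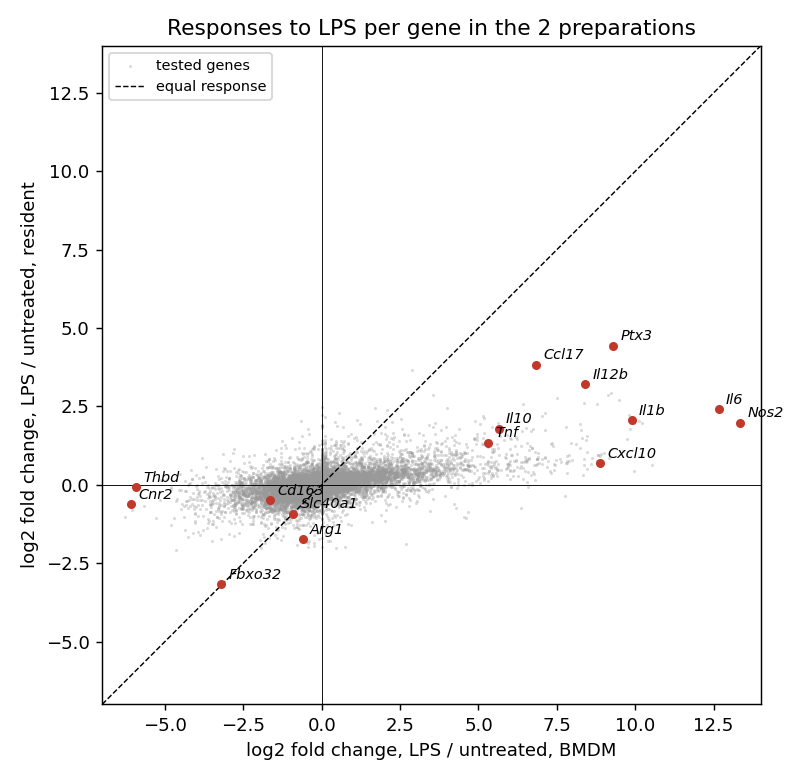
Log2 change after LPS for each tested gene, BMDM on the horizontal axis and resident macrophages on the vertical axis, with named genes in red and a dashed line of equal response. Across genes, which are not independent replicates, Pearson's r is 0.55 and Spearman's rho 0.52, and Nos2, Il6 and Il1b lie far below the line.

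Whether the LPS response differs between the origins was tested as the difference of the changes, resident minus BMDM. The inflammatory genes that LPS raised most in BMDM rose less in resident macrophages. The difference was -11.38 ± 0.74 for Nos2, -10.26 ± 0.78 for Il6, -8.19 ± 0.24 for Cxcl10, -7.83 ± 0.24 for Il1b and -3.96 ± 0.19 for Tnf (n = 3, 3, 2 and 2). Vcam1 (-4.56 ± 0.23) and Spic (-2.38 ± 0.21), which were high in resident macrophages with or without LPS, also differed. In the other direction, Thbd stood at 417 ± 105 and 387 ± 32.7 in resident macrophages while it fell in BMDM, a difference of 5.84 ± 0.32, and Cnr2 (5.45 ± 0.42), Bmf (5.32 ± 0.41), Pald1 (5.24 ± 0.22) and Plekhg3 (4.97 ± 0.24) followed.

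Other fixed genes with a called difference were Il12b (-5.20 ± 0.46), Il10 (-3.85 ± 0.61) and Tlr4 (-0.71 ± 0.15), whose call was lost with quantile normalization (-0.29) and equal totals (-0.22). The difference for Cd163 was 1.14 ± 0.39 (adjusted p = 0.0374), and it was not called in 12 other settings, among them those without resident untreated replicate 2 (0.92), resident untreated replicate 3 (1.07), resident LPS replicate 1 (0.97), resident LPS replicate 3 (1.16), BMDM untreated replicate 1 (1.32), BMDM untreated replicate 2 (0.96), BMDM LPS replicate 1 (1.12) and BMDM LPS replicate 2 (1.16). Slc40a1 (-0.02 ± 0.24), Hmox1 (0.18 ± 0.30), Adgre1 (-0.46 ± 0.32, or 0.39 with quantile normalization and 0.03 with equal totals) and Cd14 (-1.05 ± 0.47) were not called. Cd14 was called without resident untreated replicate 3 (-1.29) or resident LPS replicate 1 (-1.30), but had -0.68 without resident untreated replicate 1, -0.07 with quantile normalization and -0.56 with equal totals. The fitted difference for Ifnb1 was -4.86 ± 0.34 (-2.55 at a pseudocount of 10), and this value depends on the floor that untreated BMDM were at. With that floor taken as 3 reads per library it was -3.96. Among the largest negative differences were Cxcl11 (-9.90 ± 0.46), Cxcl9 (-9.53 ± 0.33), Gbp5 (-8.55 ± 0.25), Ccl5 (-8.31 ± 0.43), Il27 (-8.27 ± 0.38) and the early activation gene Cd69 (-8.25 ± 0.19).

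All 47 type I interferon response genes had a smaller change in resident macrophages, with a median difference of -5.26 (47 adjusted over the list alone, adjusted p = 1.44e-149, adjusted p = 0.203 with an estimated correlation). So did 23 of 24 proinflammatory cytokine genes (median -4.92, or -4.84 with genes at the floor at their bound, adjusted p = 3.79e-26, adjusted p = 0.203 with an estimated correlation). Smaller changes were called in 18 of 23 chemokine genes (median -4.74, adjusted p = 5.17e-16, adjusted p = 0.284 with an estimated correlation) and 31 of 33 NF-kB feedback genes (median -2.53, adjusted p = 7.5e-35, adjusted p = 0.267 with an estimated correlation). Antimicrobial genes had 15 lower and 1 higher of 26 (median -1.69, adjusted p = 4.61e-12, adjusted p = 0.203 with an estimated correlation). TLR signalling genes had 28 lower and 5 higher of 41 (median -0.91, adjusted p = 6.9e-10, adjusted p = 0.203 with an estimated correlation). Antigen presentation genes had 13 lower of 22 (14 adjusted over the list alone, median -1.02, adjusted p = 4.34e-08, adjusted p = 0.47 with an estimated correlation). Anti-inflammatory genes had 13 lower and 4 higher of 24 (median -0.85, adjusted p = 0.00161, adjusted p = 0.47 with an estimated correlation). Complement genes had 7 lower and 1 higher of 22, with a median of -0.45 that turned to 0.01 with quantile normalization and 0.04 with equal totals (adjusted p = 0.00525, adjusted p = 0.488 with an estimated correlation). Glycolysis and hypoxia genes had 18 lower and 2 higher of 25 (median -0.86, adjusted p = 0.026, adjusted p = 0.203 with an estimated correlation). That call was lost without resident untreated replicate 2 (-0.79, adjusted p = 0.0536) or BMDM untreated replicate 2 (-0.86, adjusted p = 0.0559), and with quantile normalization (-0.16). The fall of cell cycle genes in BMDM was not matched in resident macrophages. There, 26 of 39 differed upward and 2 downward (30 and 2 adjusted over the list alone, median 1.16, adjusted p = 0.000349, adjusted p = 0.746 with an estimated correlation), as in Kif23 (2.56 ± 0.37) and Rrm2 (2.29 ± 0.42). Cholesterol and lipid genes differed upward in 16 and downward in 1 of 32 cases (median 0.48, adjusted p = 0.00161, adjusted p = 0.267 with an estimated correlation), with Scd2 at 3.32 ± 0.29.

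Of the genes called in both LPS comparisons, 894 rose in both, where 286.9 are given by independence, and 589 fell in both, against 225.9, while 62 went in opposite directions. Of the 2187 genes that rose at least 2-fold in BMDM, 1971 had a called smaller change in resident macrophages; their median change was 2.10 in BMDM and 0.34 in resident macrophages. These genes were chosen by their change in BMDM, which is part of the difference, so the choice itself favours this direction. Limma called 5752 genes for the difference, 2617 upward and 3135 downward. Equal totals put the median difference of all genes at 0.48 and quantile normalization at 0.14, against 0.02. The share of called genes that differed upward was then 75.2% and 56.9%, against 45.5% with the deposited values.

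The comparison of untreated resident macrophages with untreated BMDM asks how the origins differ before stimulation. The genes that mark resident bone marrow macrophages were far higher in the retained cells. Cd163 stood at 7503 ± 2867 against 47.9 ± 8.48 (n = 3 and 2), a difference of 7.21 ± 0.27. Vcam1 stood at 71494 ± 14982 against 482 ± 70.1 (7.20 ± 0.16), Spic was higher by 8.46 ± 0.15, Slc40a1 by 4.59 ± 0.17 and Hmox1 by 4.04 ± 0.21. Inflammatory genes were also higher without any LPS: Il1b by 6.74 ± 0.17, Cxcl10 by 6.99 ± 0.17, Il6 by 6.66 ± 0.55, Nos2 by 5.81 ± 0.53, Il10 by 4.90 ± 0.43 and Tnf by 3.83 ± 0.14, and Ifnb1 was at least 34.6-fold higher than the floor of 3 reads per library in BMDM. Il12b was higher by 1.41 ± 0.33 (0.28 and not called with quantile normalization), Tlr4 was lower (-0.52 ± 0.11, or -0.82 with quantile normalization), and Cd14 (0.13 ± 0.34) was not called. Gpnmb, a glycoprotein gene of lipid-laden macrophages, stood at 2230 ± 936 in resident macrophages and 347678 ± 2147 in BMDM (-7.36 ± 0.40), and the macrophage elastase gene Mmp12 was lower by -6.98 ± 0.50.

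Transcripts of other marrow cells were among the largest differences. The neutrophil granule genes Camp (24518 ± 7834 against 12.3 ± 8.41, 10.95 ± 0.36), Ltf (10.47 ± 0.60), Retnlg (10.46 ± 0.23) and Ngp (93910 ± 27046 against 84.9 ± 40.2, 10.13 ± 0.29) were higher in the resident libraries, as were the beta globin genes Hbb-b1 (15947 ± 3356 against 8.22 ± 3.89, 10.80 ± 0.26) and Hbb-bs (10.51 ± 0.23). Hbb-b2 and Hbb-bt hold identical values in every library, and were at least 1099-fold above the floor of 3 reads per library.

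All 33 neutrophil genes were higher in the untreated resident libraries, with a median of 7.83, or 7.64 with genes at the floor at their bound (adjusted p = 7.01e-36, adjusted p = 0.291 with an estimated correlation). Erythroid genes were higher in 31 of 32 cases (5.20, or 4.54 at the bound, adjusted p = 7.16e-28, adjusted p = 0.291 with an estimated correlation). B lineage genes were higher in 18 and lower in 1 of 19 cases (4.75, or 4.16, adjusted p = 2.04e-05, adjusted p = 0.315 with an estimated correlation). Megakaryocyte and platelet genes were higher in 18 of 19 (4.96, adjusted p = 0.00107, adjusted p = 0.463 with an estimated correlation). Stem and progenitor genes were higher in 15 of 15 (2.99, or 2.65, adjusted p = 0.00349, adjusted p = 0.292 with an estimated correlation). Stromal and bone genes were higher in 20 and lower in 1 of 23 cases (4.08, adjusted p = 0.000905, adjusted p = 0.298 with an estimated correlation). Eosinophil, basophil and mast cell genes were higher in 15 and lower in 1 of 17 cases (16 and 1 adjusted over the list alone, 3.27, adjusted p = 2.04e-05, adjusted p = 0.291 with an estimated correlation). T and NK cell genes were higher in 17 and lower in 2 of 19 (3.20, or 2.70, adjusted p = 0.0105, adjusted p = 0.292 with an estimated correlation). Plasma cell genes were higher in 6 and lower in 1 of 8 (1.33, adjusted p = 0.0164, adjusted p = 0.291 with an estimated correlation). Monocyte genes were higher in 10 and lower in 3 of 15 (2.05, adjusted p = 0.000261, adjusted p = 0.473 with an estimated correlation). Dendritic cell genes (11 higher and 3 lower of 17) and osteoclast genes (6 and 4 of 11, median 1.49, or 0.58 at the bound, and -0.16 with quantile normalization) did not pass the test.

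The neutrophil list took 1.38% ± 0.476 of all values in untreated resident libraries, 1.58% ± 0.154 in LPS-treated resident libraries, and 0.0121% and 0.0339% in untreated and LPS-treated BMDM. In BMDM its members Lcn2 (5.16) and Hdc (8.48) rose with LPS, so the change of the share there is no measure of neutrophils. The erythroid list took 0.266% and 0.281% in the resident groups and 0.0115% and 0.0179% in BMDM. In the other direction, the stromal and bone list took 0.0664% of untreated resident libraries and 0.235% of untreated BMDM. The plasma cell list took 0.0378% and 0.0742%, and the dendritic list 0.248% and 0.291%. Stromal and plasma cell lists each had 1 called lower member, Spp1 (-3.84) and Sdc1 (-4.32), while most members were higher in resident libraries. Their larger shares in BMDM are thus no measure of such cells. Within the resident groups, the neutrophil share was lowest in replicate 1 of each: 0.881% against 1.44% and 1.83% untreated, and 1.41% against 1.68% and 1.67% with LPS. Of the 10 lists of other cell types examined for this, 6 had their lowest mean log2 value in replicate 1 of both groups: neutrophil, B lineage, T and NK, megakaryocyte, stem and progenitor, and eosinophil, basophil and mast cell.

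**Figure D3:**
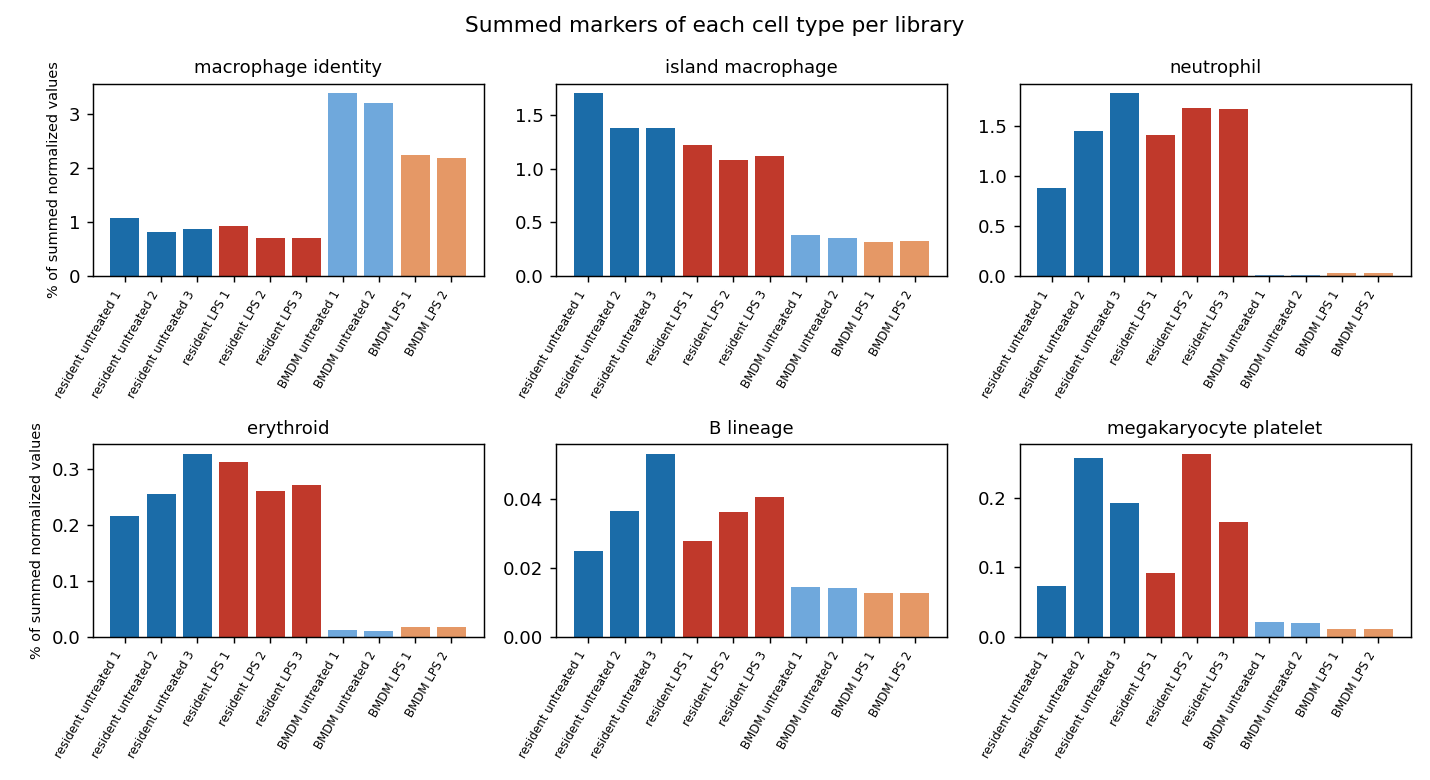
Percent of the summed normalized values that each of 6 marker lists takes in each library. The neutrophil list takes 0.881% to 1.83% of the untreated resident libraries and a mean of 0.0121% of untreated BMDM, and the macrophage identity list a mean of 0.921% and 3.30%.

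Among lists of macrophage functions, island macrophage genes were higher in resident cells in 18 and lower in 2 of 22 cases (median 2.84, adjusted p = 1.33e-14, adjusted p = 0.292 with an estimated correlation), with the engulfment receptor gene Timd4 at 7.52 ± 0.23. Iron handling genes were higher in 18 and lower in 7 of 31 cases (0.55, adjusted p = 0.00343, adjusted p = 0.528 with an estimated correlation). The largest rises in that list were Lcn2 (9.33), which is also in the neutrophil list, and Hp (7.47). Of its 31 genes, 9 are in another list. Macrophage identity genes were higher in 4 and lower in 10 of 15 cases and did not pass (median -0.80, mean -0.00): Mrc1 was higher by 2.80 ± 0.20, while Lyz2 (-2.75 ± 0.24), Ctss (-2.77 ± 0.27) and Adgre1, the F4/80 antigen gene (-1.08 ± 0.23), were lower.

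All 47 type I interferon response genes (median 4.42, adjusted p = 1.78e-77, adjusted p = 0.291 with an estimated correlation) were higher in the untreated resident libraries. So were 23 of 24 cytokine genes (4.26, adjusted p = 3.36e-17, adjusted p = 0.291 with an estimated correlation) and 32, with 1 lower, of 33 NF-kB feedback genes (2.59, adjusted p = 7.7e-25, adjusted p = 0.292 with an estimated correlation). These libraries also carry the neutrophil and erythroid transcripts. Chemokine genes were higher in 19 and lower in 2 of 23 cases (3.96, adjusted p = 3.94e-09, adjusted p = 0.315 with an estimated correlation). Antimicrobial genes were higher in 16 and lower in 7 of 26 (2.40, adjusted p = 2.97e-09, adjusted p = 0.315 with an estimated correlation). Camp (10.95) and Lcn2 (9.33) in this list are also in the neutrophil list. Anti-inflammatory genes were higher in 19 and lower in 4 of 24 (20 and 4 adjusted over the list alone, 2.99, adjusted p = 3.19e-06, adjusted p = 0.291 with an estimated correlation). Their member Chil3 (8.22) is also in the neutrophil list. Immediate-early and stress genes were higher in 20 and lower in 3 of 28 cases (1.12, adjusted p = 0.00643, adjusted p = 0.291 with an estimated correlation): Socs3 was higher by 6.47 ± 0.24 and Fos lower by -2.53 ± 0.10. Antigen presentation genes were higher in 14 and lower in 2 of 22 cases (1.17, adjusted p = 0.000261, adjusted p = 0.477 with an estimated correlation), and complement genes in 14 and 6 of 22 (2.19, adjusted p = 0.00455, adjusted p = 0.39 with an estimated correlation). TLR signalling genes were higher in 21 and lower in 10 of 41 cases (0.34, adjusted p = 0.0291, adjusted p = 0.556 with an estimated correlation), a call lost without BMDM untreated replicate 1 (0.39) or replicate 2 (0.30).

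In the other direction, cholesterol and lipid genes were lower in resident cells in 23 and higher in 7 of 32 cases (24 and 7 adjusted over the list alone, median -0.90, adjusted p = 4.15e-05, adjusted p = 0.291 with an estimated correlation), with the phospholipid transfer protein gene Pltp at -4.02 ± 0.14. Lysosome genes were lower in 20 and higher in 5 of 35 cases (-0.59, adjusted p = 0.000248, adjusted p = 0.513 with an estimated correlation), with Atp6v0d2 at -5.96 ± 0.31 and Gusb at -3.46 ± 0.08. Mitochondrial respiration genes were lower in 23 and higher in 1 of 34 cases (-0.38, adjusted p = 0.00552, adjusted p = 0.463 with an estimated correlation). Glycolysis and hypoxia genes were lower in 13 and higher in 6 of 25 (-0.31, adjusted p = 0.014, adjusted p = 0.292 with an estimated correlation). Cell cycle genes were lower in 14 of 39 cases (11 adjusted over the list alone, -0.39, adjusted p = 0.0286, adjusted p = 0.651 with an estimated correlation). Leaving out resident untreated replicate 1 gave a median of -0.12 for them and ended the call. NRF2, apoptotic cell clearance and matrix genes did not pass the test (14 higher and 5 lower of 23, 15 and 10 of 28, and 13 and 11 of 32). Limma called 9883 genes, 5393 higher and 4490 lower in resident macrophages. Quantile normalization put the median of all genes at -0.18, against 0.08, and left 41.5% of its 9928 called genes higher, against 54.6% with the deposited values.

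**Figure D4:**
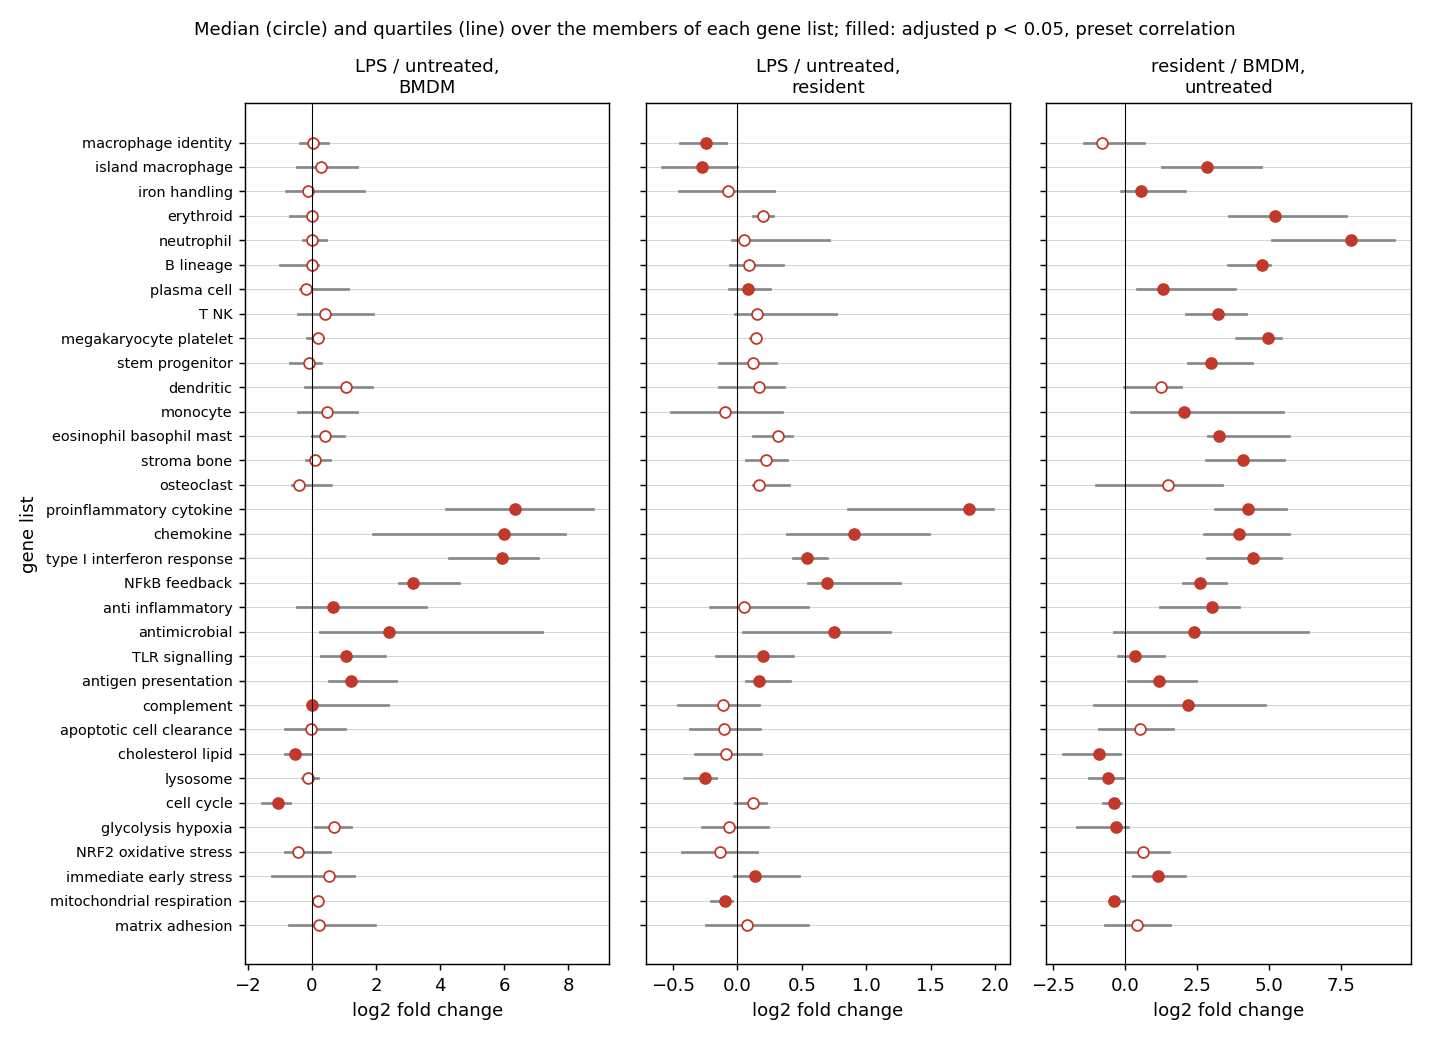
Median (circle) and quartiles (line) of the log2 differences of each of 33 gene lists for LPS in BMDM, LPS in resident macrophages, and resident against BMDM untreated, on separate scales; filled circles passed the camera test with its preset correlation and none passed with an estimated correlation. All 47 interferon response genes are higher in the BMDM and untreated panels; among filled circles the complement median in BMDM turns below 0 with quantile normalization and equal totals, and the plasma cell median in resident macrophages with equal totals.

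The comparison under LPS asks how the origins differ once stimulated. Tnf no longer differed by a called amount: it stood at 59809 ± 7369 in resident macrophages and 65021 ± 2111 in BMDM (-0.13 ± 0.14, n = 3 and 2), and turned to 0.44 with quantile normalization and 0.20 with equal totals. Nos2 (-5.57 ± 0.53), Il12b (-3.78 ± 0.33), Il6 (-3.60 ± 0.55), Cxcl10 (-1.20 ± 0.17, or -0.62 with quantile normalization) and Il1b (-1.09 ± 0.17, or -0.38) were lower in resident macrophages, as were Tlr4 (-1.23 ± 0.11) and Adgre1 (-1.54 ± 0.23). Ifnb1 went the other way and was higher by 0.70 ± 0.24 (adjusted p = 0.0216), a call lost with quantile normalization (0.52) and without resident LPS replicate 2 (0.65), resident LPS replicate 3 (0.61) or BMDM LPS replicate 1 (0.52). Cd14 was lower (-0.92 ± 0.34, adjusted p = 0.0312), a call lost in 7 other settings, among them quantile normalization (-0.25) and equal totals (-0.59). Cd163 (8.34 ± 0.27), Spic (6.09 ± 0.15), Slc40a1 (4.58 ± 0.17), Hmox1 (4.21 ± 0.21) and Vcam1 (2.64 ± 0.16) remained higher, and Csf3, the granulocyte growth factor gene, was higher by 6.88 ± 0.35. Ptgs2 (-3.93 ± 0.36), Ch25h (-5.37 ± 0.36), Tlr8 (-4.67 ± 0.12), Fcgr1 (-3.79 ± 0.10) and Cav1 (-7.19 ± 0.27) were lower, as were Gpnmb (-7.39 ± 0.40) and Mmp12 (-7.36 ± 0.50). Il10 (1.04 ± 0.43) was called at an adjusted p of 0.0497, which leaving out any of 7 libraries ended, with 0.76 without resident LPS replicate 1 as the lowest value and 1.06 without resident LPS replicate 2 or BMDM LPS replicate 1 as the highest.

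Type I interferon response genes, all higher in untreated resident macrophages, were lower in 38 and higher in 3 of 47 cases under LPS (39 and 3 adjusted over the list alone, median -0.81, adjusted p = 2.24e-05, adjusted p = 0.567 with an estimated correlation), with Gbp2 at -2.60 ± 0.19 and Slfn4 at 2.94 ± 0.24. Glycolysis and hypoxia genes were lower in 18 and higher in 2 of 25 cases (19 and 2, -0.99, adjusted p = 6.9e-07, adjusted p = 0.183 with an estimated correlation). Mitochondrial respiration genes were lower in 30 of 34 (32 adjusted over the list alone, -0.64, adjusted p = 3.69e-05, adjusted p = 0.492 with an estimated correlation). Lysosome genes were lower in 23 and higher in 3 of 35 (-1.10, adjusted p = 3.79e-05, adjusted p = 0.588 with an estimated correlation). TLR signalling genes were lower in 24 and higher in 7 of 41 (-0.44, adjusted p = 0.00044, adjusted p = 0.492 with an estimated correlation). Cytokine genes were higher in 6 and lower in 11 of 24 cases and did not pass (median -0.36). NF-kB feedback genes were higher in 10 and lower in 14 of 33, with a median of -0.20 that turned to 0.16 with quantile normalization and 0.12 with equal totals. Neutrophil genes stayed higher in 31 of 33 cases (7.49, or 7.26 at the bound, adjusted p = 1.05e-40, adjusted p = 0.479 with an estimated correlation). Erythroid genes were higher in 30 and lower in 1 of 32 (5.33, or 5.16, adjusted p = 3.75e-37, adjusted p = 0.183 with an estimated correlation), and island macrophage genes in 15 and 1 of 22 (2.06, adjusted p = 1.47e-09, adjusted p = 0.502 with an estimated correlation). Limma called 9802 genes, 5050 higher and 4752 lower, with a median of 0.03 for all genes. Equal totals put that median at 0.35 and quantile normalization at -0.09, and 68.2% and 45.5% of the called genes were then higher, against 51.5% with the deposited values.

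In the mouse genome build mm10, Cd163 lies on chromosome 6 from 124304656 to 124330527, Vcam1 on chromosome 3 from 116109949 to 116129688, Spic on chromosome 10 from 88674772 to 88685015, Nos2 on chromosome 11 from 78920787 to 78960254, Thbd on chromosome 2 from 148404466 to 148408188 and Fbxo32 on chromosome 15 from 58175879 to 58214932. All of these are annotated as protein-coding genes.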

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

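The 2 tests that regroup the resident libraries were chosen before the result was seen, and the other 6 tests in this part after it; for the X-linked genes the outcome to look for was written before their values were seen.

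The response to LPS differed between resident macrophages and BMDM for 5752 genes by limma's test of the difference itself. Among the fixed genes the difference in log2, resident minus BMDM, was -11.38 for Nos2, -10.26 for Il6, -8.19 for Cxcl10, -7.83 for Il1b, -5.20 for Il12b, -4.86 for Ifnb1, -4.56 for Vcam1, -3.96 for Tnf, -3.85 for Il10, -2.38 for Spic, -0.71 for Tlr4 and 1.14 for Cd163. Among the genes with the largest differences it was -9.90 for Cxcl11, -9.53 for Cxcl9, -8.55 for Gbp5, -8.31 for Ccl5, -8.27 for Il27 and -8.25 for Cd69, and it was 5.84 for Thbd, 5.45 for Cnr2, 5.32 for Bmf, 5.24 for Pald1, 5.12 for Kazald1, 4.97 for Plekhg3, 4.88 for Palm3 and 4.67 for Galnt9. List medians of the difference were -5.26 for interferon response genes, -4.92 for cytokines, -4.74 for chemokines, -2.53 for NF-kB feedback, -1.69 for antimicrobial genes, -1.02 for antigen presentation, -0.91 for TLR signalling, -0.86 for glycolysis and hypoxia, -0.85 for anti-inflammatory genes, -0.45 for complement, 0.48 for cholesterol and lipid genes and 1.16 for cell cycle genes. The difference for Ifnb1 depends on the floor that untreated BMDM were at, and it was -3.96 with that floor taken as 3 reads per library. Palm3 and Galnt9 were at or near the floor and Kazald1 was low in the resident libraries, so a fall with LPS could not be seen there and their differences rest on the fall in BMDM. At a pseudocount of 10 the difference was 3.16 for Kazald1 and 2.42 for Palm3. None of these lists passed with an estimated correlation, where the lowest adjusted p was 0.203. Complement turned to 0.01 with quantile normalization.

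For the smaller response of resident macrophages, the scaling of the libraries is argued against, since the highest median difference of responses over the 126 cytokine, chemokine, interferon and NF-kB genes of the lists was -3.46 under the 3 other scalings. Of the 3, recomputed median-ratio factors nearly repeat the deposited scaling (-4.02 for both), so this rests on quantile normalization (-3.46) and equal totals (-3.55). The 126 genes stood higher in untreated resident macrophages, with a median difference of 3.59 and a lower quartile of 2.56. These transcripts may have been raised before LPS was added, by handling or in the marrow, and the immediate-early and stress list had a median difference of 1.12 between the untreated groups. Of that list 20 genes were higher and 3 lower. The heat shock gene Hspa1a was higher by 4.22 and Fos was lower (-2.53), while Socs3, which was higher, is also in the NF-kB list. The list cannot separate handling from cell origin, because isolation, culture and cell origin change together in this design. A difference in the biology of the cells stays open as untested. Cells that lack the induced transcripts would lower values with and without LPS alike, and dilution by them was not tested. That does not cover other marrow cells in the fraction that carry these transcripts themselves. How much of the values with or without LPS comes from such cells was not measured, so a part of them in the smaller change is open.

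Transcripts of other marrow cells stood out in the resident libraries, and a candidate source is RNA of such cells in the fraction that the column retained without staining. Of 198 tested genes in 10 lists of other cell types, 180 were called higher and 9 lower in untreated resident macrophages (90.9% higher), a count that restates the pattern and leaves its source open. The lists of monocytes (10 higher, 3 lower) and osteoclasts (6 higher, 4 lower), cell types close to macrophages, were left out, and 17 of the 198 genes are also in a list of another kind. Scaling is argued against, since the lowest median difference of the 198 genes was 3.52 under the 3 other scalings. Recomputed median-ratio factors nearly repeat the deposited scaling, so this rests on quantile normalization (3.52) and equal totals (4.11). Engulfment of other cells by the macrophages would bring the same RNA and was not tested, and no sort on CD163 that would remove other cells is described.

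Replicate 1 of both resident groups stood apart from the other libraries. The Y-linked genes were read there (Ddx3y at 1856 and 1975) and were at the floor in every other library. Both libraries therefore hold RNA of cells with a Y chromosome. Xist was read there as well, at 1651 and 2172, and the part of their RNA that is male was not measured. Of 4 X-linked genes that escape X inactivation, 3 (Kdm5c, Kdm6a and Eif2s3x) were lower in replicate 1 than in both others in both treatments. Ddx3x was so with LPS only. This leaves undecided whether male RNA accounts for other differences of these libraries. Fewer cells of other types in these libraries was tested on 10 lists, of which 6 were lowest in replicate 1 in both treatments, while erythroid, plasma cell, dendritic and stromal genes were so in 1 treatment. This explanation is undecided as well. The labels give neither the sex of the animals nor a batch.

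Of the 10 splits of the 6 resident libraries into 3 and 3, 1 gave as many called genes as the real split, which is the real split itself (1779), and the highest of the others gave 0 by limma. At an unadjusted p under 0.05 the real split gave 3793 genes and the highest of the others 2446. For the gene lists, 6 of the 10 splits gave as many as the real split (13), and the highest other gave 21. The split with 21 lists puts the libraries with Y-linked transcripts together on a side with LPS replicate 3. With 10 splits no share under 0.05 can be reached. Every split but the real one also mixes untreated and LPS-treated libraries on both sides, in unequal numbers. Part of the LPS effect thus stays in the comparison and the rest widens the spread. The counts of the other splits are therefore not counts without an LPS effect, for genes or for lists, and nothing is concluded from them.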

How the results depend on the processing

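Chosen after seeing the data were equal totals, voom, the term for Y-linked transcripts and leaving out both libraries with them. Counts stayed within 1.5 times their value under the alternatives run, except as given here; unless a cause is named, the cause was not tested. Requiring a log2 change of at least 1, which is stricter, gave 311 genes for LPS in resident macrophages, 4309 for LPS in BMDM, 5470 and 5288 for resident against BMDM untreated and with LPS, and 3433 for the difference. For LPS in resident macrophages the count was 529 with the groups compared alone. It was 3449 with the Y-linked term and 2840 without these libraries. For LPS in BMDM the groups compared alone gave 9521 against 7953, so fewer libraries need not lower a count. Leaving out each library in turn gave 970 (without resident LPS replicate 2) to 2287 (without resident untreated replicate 1) for LPS in resident macrophages, 6408 to 8536 for LPS in BMDM, 8367 to 10058 and 8370 to 10285 for resident against BMDM, and 4303 to 5951 for the difference. In a group of 2 this leaves 1 sample, which is assumed to vary like the other groups.

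Of the lists, camera with an estimated correlation called 0 in each of the 5 contrasts (13, 11, 27, 17 and 12 with the preset), with 3, 6, 3, 2 and 6 at an unadjusted p under 0.05. The fry test gave 22 for LPS in BMDM, 29 for resident against BMDM with LPS and 19 for the difference. Leaving out each library gave 11 to 15, 11 to 12, 26 to 28, 17 to 19 and 11 to 14. No list call reversed under any alternative.

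Of 595 gene results, quantile normalization left 558 on the same side of the threshold with the same direction, equal totals 567, voom 569, array weights 579 and pseudocount 10 579. Reversed values, with array weights, were 0.077 (Vcam1) and 0.10 (Adgre1) for LPS in resident macrophages, -0.10 for Cd14 (untreated) and 0.15 for Slc40a1 (difference). Without both libraries with Y-linked transcripts they were 0.087, 0.096, -0.24 and 0.029, and Cd14 had -0.18 with the Y-linked term. With quantile normalization they were -0.093 for Spic (LPS in resident macrophages), -0.55 for Adgre1, -0.016 for Blnk, -0.15 for Nr1h2, -0.45 for Srebf2 and -0.066 for Uqcrc2 (LPS in BMDM), -0.18 for Cd14 and -0.14 for Uqcrc2 (untreated), 0.44 for Tnf (with LPS) and 0.39 for Adgre1 (difference). With equal totals they were -0.046 for Spic, -0.16 for Adgre1, -0.28 for Nr1h2, -0.30 for Srebf2, -0.066 for Uqcrc2, -0.033 for Cd14, 0.20 for Tnf and, for the difference, 0.47 for Slc40a1, 0.027 for Adgre1 and 0.056 for Nr1h2. Leaving out each library gave -0.10 to 0.15 for Vcam1, -0.017 to 0.26 for Spic and -0.16 to 0.24 for Adgre1 (LPS in resident macrophages), -0.24 to 0.38 for Cd14 (untreated), and -0.19 to 0.13 for Slc40a1 and -0.0050 to 0.36 for Hmox1 (difference).

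The planned count tests on recovered reads were not run. No paired analysis was run, because replicate numbers follow only the order of accessions and no label links libraries of different groups. Y-linked transcripts are nevertheless shared by a library of each resident group. A term for these libraries raised the count for LPS in resident macrophages to 3449 genes, against 1779 in the main fit, which left this shared difference out. Whether the other resident libraries belong together across treatments was not tested. Chi-square per degree of freedom between replicates was 4.27 to 99.5, so the spread between replicates is wider than read counting gives. The 99.5 belongs to untreated BMDM, where Rn45s took 0.232% and 4.70% of values, and it was not computed without that gene. The next highest was 85.9, for resident untreated replicates 1 and 3.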

Other observations

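The genes below were chosen after their values were seen, and the values are reported without a test of a cause. LPS moved 62 genes in opposite directions in the 2 origins, with both changes called, beside 894 genes called upward and 589 called downward in both. Of the 62, 29 rose in resident macrophages and fell in BMDM: Gpr183 (0.85 and -3.82), Thbs1 (1.00 and -2.83), Myc (0.46 and -2.68), Nr4a1 (0.51 and -2.63), Kcnj2 (0.61 and -2.28), Enc1 (0.96 and -2.15) and Ctsk (0.97 and -0.48) are examples. The other 33 fell in resident macrophages and rose in BMDM, such as Ly6e (-0.31 and 2.40), Fcgr1 (-0.57 and 2.05), Maf (-0.44 and 1.61), Siglec1 (-0.59 and 0.95), Tlr8 (-0.72 and 0.91) and Mmp9 (-0.57 and 0.87). Quantile normalization and equal library totals put the median change of all genes in BMDM at -0.21 and -0.64, against -0.04, so they favour falls and bear on the rises alone. Of the 33 genes, 20 kept opposite signs under both. The rise in BMDM was then 1.67 and 1.79 for Ly6e, 1.19 and 1.44 for Fcgr1, 0.89 and 0.99 for Maf, 0.51 and 0.33 for Siglec1, 0.073 and 0.30 for Tlr8, and 0.97 and 0.26 for Mmp9.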
